A study of Homo sapiens with 2 samples.

How the data were processed

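Poly(A) RNA was sequenced from 2 cultures of HCT116, a human colorectal carcinoma cell line, carrying a tetracycline-inducible construct against USP49. Per the labels' protocols, mRNA was enriched on oligo(dT) beads, sheared, copied with random hexamers and ligated to adapters, with no step described that marks the strand. There was 1 control library and 1 library labelled USP49 knockdown, taken 36 h after doxycycline per the labels' protocols. The treatment labels read control and USP49 knockdown, while the treatment protocol text is the same for both libraries. For the chromatin experiments the labels call the control cells uninduced, and for the RNA control they do not say. The labels' protocols also describe chromatin immunoprecipitation of ubiquitinated and total H2B, which was not analysed here.

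The deposited files were transcript assemblies made by Cufflinks per library, guided by RefSeq transcripts, per the file headers and columns. The submitters' processing notes name TopHat, Bowtie, SAMtools, Picard, Cufflinks and bedtools, and the genome build hg18; their versions are not given in the sources used here. All coordinates below are 1-based hg18 positions as the files give them. Each library was assembled on its own, so 1 gene can be carried by a RefSeq model in one library and by an assembled model of another length in the other. That choice of models sets any value that is summed over models.

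Each model in the deposited files carried a value named FPKM with the bounds of an interval. The values proved not to be divided by sequencing depth, by the relation given below. The highest were 1.57e+13 in the control library and 4.62e+13 in the library labelled knockdown, which do not show this by themselves. In loci with 1 model, the interval gave back a fragment number, taking it as the value ± 2 Poisson SD. That number was whole, within 0.02, for 17351 of 18291 such loci in the control library (94.9%) and 18555 of 19627 in the library labelled knockdown (94.5%). The value was then proportional to the fragment number divided by 2 × (length − 47 bases), with no term for depth. Unspliced assembled models followed a larger length correction of 245.9 bases in the control library and 252.2 bases in the library labelled knockdown. Fragment numbers were recovered from this relation for every model. They summed to 16331614 in the control library and 19910907 in the library labelled knockdown over chromosomes 1 to 22, X and Y, a ratio of 1.22. The deposited FPKM and their intervals were scaled to these totals. The design fixed beforehand had assumed FPKM comparable between libraries as deposited, so this scaling was added because the unit needed it, and the values without it were kept as an alternative. Intervals cover counting error only, as copies made by PCR are not independent molecules.

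RefSeq accessions were matched to current symbols by accession in a table of the GRCh38.p14 annotation, used for names only. Of 40716 accessions, 39392 were named by accession, 529 took the symbol in the files and 795 had none. An assembled model with introns was named where it shared an intron, on the same strand, with RefSeq models of 1 symbol; this rule was set after the files were seen. Of the genes in the fixed lists, 18 had no current symbol and were left out. Genes with a near-identical copy, or sharing exonic bases with another gene, are uncertain, since the assembly may divide their fragments in either way.

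The planned gene value was the sum of depth-scaled FPKM over the named models of a gene. The ratio was log2 of the value in the library labelled knockdown plus a pseudocount of 1 FPKM over the control value plus 1, which understates changes of low genes. Genes with a mean of 1 FPKM or more were counted, and 2-fold was the threshold of size. After the planned counts had been seen, 4 more gene measures were tried, in this order. The first was the fragment density on a gene's RefSeq exons from models of the gene's strand, for genes with 300 or more exonic bases. The next took models of either strand. Both densities spread each model's fragments evenly over its length, as the assemblies hold no read positions. They therefore still rest on the models of each library. The third kept only genes whose fragments lay on models with the same introns in both libraries, counting models with 5% or more of the gene's fragments. Model ends were not compared there; unspliced RefSeq models were matched by identity, and unspliced assembled models were all taken as alike. The last also asked for lengths within 10%, except of unspliced assembled models, and was added after GLRX2 had stood out under the looser rule. The counts under all 5 measures are in the results, and the planned sum stays the main value.

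With 1 library per group no difference has a replicate check, and no p-value was computed. The design fixed before the data were examined named USP49 first. It then took the 12 lowest and 12 highest ratios among genes of mean FPKM 5 or more, above 0 in both libraries and with intervals that do not overlap. It added up to 4 members of each gene list with the largest ratio in either direction, of which 2 are not reported here, and the most different exons and introns. The 6 exons and 4 introns with the largest fall and the 4 exons and 2 introns with the largest rise were taken among events of summed FPKM 10 or more, 1 per gene. Many events tied at a difference of 100 percentage points (18 falls and 26 rises of exons, 29 and 33 of introns), and ties were ordered, by a rule set after the files were seen, by the smaller of the event's summed FPKM in the libraries. Genomic span and exon number were taken from the longest RefSeq model. Genes whose levels would report on donor sex were left out.

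There were 34 gene lists fixed beforehand, listed by name in the results. For each list with 5 or more measured members, the median ratio was placed among 10000 random lists of the same size matched on mean FPKM in 20 bins; a list was called when its percentile was under 2.5 or over 97.5. This describes these 2 libraries only. Exon inclusion was the summed FPKM of the models holding an internal exon over that sum plus the FPKM of models with an intron spanning it. Intron retention was computed likewise. For exons, introns and the most abundant transcript, an assembled model that joins 2 or more genes was counted under each of them. The planned gene sum leaves such models out, so the summed FPKM of a gene can differ between these steps. Both needed a summed FPKM of 5 or more in each library, and a difference of 10 percentage points was counted. The most abundant transcript of a gene was called different where both top transcripts held 50% or more of the gene in their library. Models of the libraries were merged only where all exon coordinates matched.

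Settings fixed beforehand as alternatives were pseudocounts of 0.1 and 5, centring on the median ratio, upper-quartile scaling, conversion to TPM, other minimum FPKM, a ratio of 1.5, intervals that do not overlap, the most abundant transcript, other event minimums, a difference of 20 points and leaving out minor transcripts. Alternatives chosen after seeing the data were the 4 gene measures above, values without depth scaling, RefSeq models only, and events with both forms above 0 in both libraries. The median and outer percentiles of all gene ratios were taken as unmoved within 0.1 on the log2 scale, a correlation within 0.05 and a count within 1.5 times. A list was unmoved if it stayed called or not called, and a named gene if it stayed past 2-fold in the same direction. The USP49 ratio was unmoved within the bounds its intervals allow. A change of sign in a called list, a named gene or USP49 was marked as reversed. These limits were set after the files were seen.

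Counting noise was simulated by drawing 100 pairs of libraries from the control models at the observed depths. This leaves out the error of assigning fragments to models and differences between the assemblies. The gene counts were tested on simulated data on chromosomes 1 to 6. With the planned sum over 4350 genes, 100 of 100 genes simulated at 3-fold passed 2-fold, as did 0 of 100 at 1.5-fold and 13 of 4150 unchanged genes. With the exon density over 4580 genes, 98 of 100 genes at 3-fold passed. Both simulated libraries held the same control models, without unspliced assembled ones. Differences between the assemblies were thus not simulated, and these rates do not cover them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.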

Results

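RNA sequencing compared a control library of HCT116 cells, a human colorectal carcinoma line, with a library of the same line labelled as an induced knockdown of USP49, a ubiquitin-specific protease that removes ubiquitin from histone H2B. The study asked how gene expression differs between them. One comparison followed from the design, of 1 control library with 1 library labelled USP49 knockdown, harvested 36 h after doxycycline. The control library held 16331614 fragments on chromosomes 1 to 22, X and Y, and the library labelled knockdown 19910907. There were no replicates, so every difference is between these 2 libraries, has no replicate check, and carries counting error only. Values are FPKM scaled to these totals, and ratios are log2 of the library labelled knockdown over control with a pseudocount of 1.

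USP49 was reported first, as a check of the labels. The gene lies on the minus strand of chromosome 6 at 41873361 to 41971077 (hg18). Its summed FPKM was 2.89 in control (interval 2.24 to 3.55) and 1.11 in the library labelled knockdown (0.841 to 1.37), a log2 ratio of −0.89 with intervals that do not overlap. The direction changed with the gene measure. Density on the RefSeq exons of USP49 was 0.905 FPKM in control (0.688 to 1.12) and 1.11 in the library labelled knockdown (0.841 to 1.37), a log2 ratio of 0.15 with overlapping intervals. In control the RefSeq model was listed at 0, and 2 assembled models named USP49, both reaching past its end to 41869189, held 115 and 91 fragments. The control exon density spreads these fragments evenly over both models, which puts 46.5 of them on RefSeq exons. The reversed direction on exons is therefore not a separate check. In the library labelled knockdown the RefSeq model held 69 fragments, and an unspliced model with no gene name and no strand, at 41869241 to 41872044, held 168. That model lies outside the RefSeq span, but all of its 2804 bases lie in exons of the control models named USP49. On models named USP49 there were 206 fragments in control and 69 in the library labelled knockdown, a depth-scaled ratio of 0.27 (exact 95% interval 0.21 to 0.36). With the 168 fragments of the unnamed model counted as USP49 there were 206 and 237, a ratio of 0.94 (0.78 to 1.14). The planned sum and the count on named models take in the bases of the unnamed model in control only. Their fall therefore does not compare like with like. The files do not tell whether the 168 fragments belong to USP49, so the label was neither borne out nor ruled out. Directions below therefore refer to the library by its label, not to a measured loss of USP49.

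**Figure D1:**
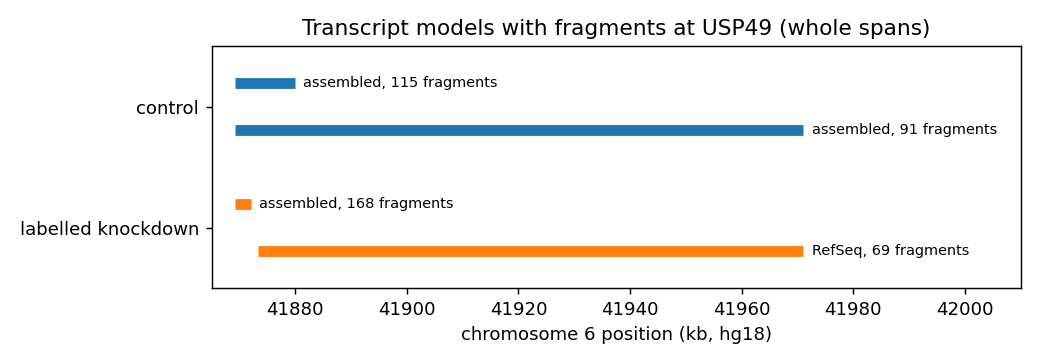
Transcript models with fragments at USP49 on chromosome 6 (x axis, position in kb, hg18), in the control library (blue) and the library labelled knockdown (orange). Each bar spans a model from start to end, introns included, with its kind and fragment number beside it; the control models hold 115 and 91 fragments and the others 168 and 69.

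Transcript levels in the libraries were close to each other. Across 11645 genes with a mean of 1 FPKM or more, the median log2 ratio was −0.0023, and 2.5% of genes lay below −0.81 and 2.5% above 0.75. Across genes, which are not independent replicates, log2 values had a Pearson r of 0.954 and a Spearman rho of 0.973. By the planned sum over named transcripts, 184 genes were 2-fold or more higher and 212 lower in the library labelled knockdown, of which 172 and 187 had intervals that do not overlap. Measured as density on RefSeq exons with models of the gene's strand, the counts were 52 higher and 77 lower of 11774 genes. With models of either strand they were 37 and 58 of 12093. Among 4387 genes carried by models with the same introns in both libraries, whatever the ends of these models, they were 1 and 3, and among 3910 with model lengths within 10% they were 1 and 2. These 4 measures were chosen after seeing the planned counts. The last 2 leave out genes whose models differ between the libraries, so their low counts follow partly from that choice. Of the 396 genes past 2-fold by the sum, 67 (16.9%) were past 2-fold in the same direction on their exons on either strand, and 261 lay within 0.5 of no difference. The spread narrowed too: on exons of either strand, 2.5% of genes lay below −0.31 and 2.5% above 0.25, with an r of 0.989.

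**Figure D2:**
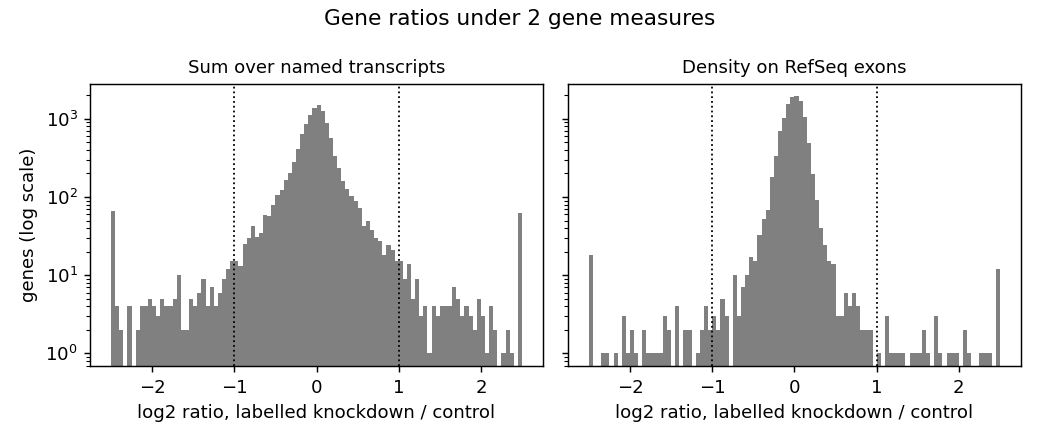
Log2 ratios of genes of mean 1 FPKM or more (x axis; library labelled knockdown over control) against the number of genes (y axis, log scale), by the planned sum (left) and by density on RefSeq exons of either strand, with no minimum of exonic bases (right), and dotted lines at 2-fold. Values beyond the axis range are drawn in the end bars; the left panel is the wider, with 184 genes higher and 212 lower past 2-fold.

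Among 1911 eligible genes, the lowest ratio was that of H1-10, a linker histone gene with 1 exon on chromosome 3 at 130516304 to 130517810. It stood at 41.8 FPKM in control and 6.02 in the library labelled knockdown, a log2 ratio of −2.61. On its exon the values were 41.8 and 37.2 FPKM, a ratio of −0.17. Next came LRPAP1, a chaperone of lipoprotein receptors, at 78.5 and 13.5 FPKM (−2.46), with −0.09 on exons. GLRX2, a mitochondrial glutaredoxin on chromosome 1 at 191332218 to 191341867, stood at 36.0 and 7.55 FPKM (−2.11), with 18.7 and 4.20 FPKM on exons (−1.92), the only 1 of the 24 named genes past 2-fold there. Its models held more fragments in the library labelled knockdown, 1893 against 385. The single model there had 12642 exonic bases, against 751 and 577 for the 2 control models, and the exon density spreads its fragments evenly over that length, so the exon value is not a separate check. POLR2L, a subunit shared by RNA polymerases, had a ratio of −1.96 by the sum and −0.03 on exons. The transcriptional repressor E2F6 stood at −1.87 and −0.02, and the endosomal GTPase RAB5B at −1.84 and −0.17. For KRT10, a keratin, the ratio was −1.73 by the sum and 0.31 on exons. NBPF1, a member of a family of near-identical copies and so uncertain, stood at −1.72 and −0.19, and DESI2 at −1.70 and 0.09. The ribosomal protein gene RPL6 had −1.68 by the sum and −0.51 on exons, at 19.9 and 13.7 FPKM. ATP5MC3, a subunit of ATP synthase, had −1.67 and −0.12, and the complement inhibitor CD59 −1.64 and 0.02.

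The highest ratio was that of CISD2, an iron-sulfur protein gene on chromosome 4 at 104009576 to 104033412, which shares bases with another gene. Its sum was 5.87 FPKM in control and 61.3 in the library labelled knockdown, a log2 ratio of 3.18, while its exon density was 6.28 and 6.78 FPKM (0.10). UQCRQ, a subunit of respiratory complex III, stood at 31.0 and 186 FPKM (2.55), with 0.21 on exons. The kinetochore gene NSL1 had 2.33 by the sum and 0.06 on exons, and MRPL19, of the mitochondrial ribosome, 2.04 and 0.12. METRNL stood at 1.89 and 0.02, ARL3, a small GTPase of cilia, at 1.74 and −0.00041, and CDCA4 at 1.65 and 0.02. ZNF146 had 1.57 and 0.21, and shares bases with another gene, as does H1-10. SDHAF3, an assembly factor of succinate dehydrogenase, stood at 1.56 and 0.27. UBQLN2, a ubiquilin, had 1.54 and −0.05, NUMBL 1.52 and −0.21, and ZNF830, at 4.97 and 15.9 FPKM by the sum, −0.02 on exons. Of the 24 genes, 22 lay within 0.5 of no difference on their exons. By exon density the direction was the opposite one for KRT10, DESI2, CD59, ARL3, UBQLN2, NUMBL and ZNF830.

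Gene lists fixed beforehand were compared next. Of 34 lists, 30 had enough measured members for a percentile, of which about 1.5 would be called if members were random genes. Members of a list can vary together between any 2 cultures, which this number leaves out. By the planned sum 1 list was higher and 3 were lower in the library labelled knockdown. By density on exons of either strand, chosen after seeing the data, 4 were higher and 5 lower, the same 4 among them. All shifts of called lists were small, between −0.14 and 0.22 on the log2 scale. With TPM the median of all genes measured moved to −0.10, and list medians are to be read relative to it.

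Genes of the G2 and M phases of the cell cycle were the list called higher: 23 of 30 members lay above 0, with a median of 0.07 at percentile 98.6 among matched random lists. With TPM the median was −0.06, and the list stood at percentile 98.0. On exons the median was 0.07 at percentile 99.9. Its 4 members with the largest ratios ran both ways by the sum: CCNB1, cyclin B1, stood at 284 and 215 FPKM (−0.40), but at 196 and 215 on exons (0.14). CDC20, an activator of the anaphase-promoting complex, had −0.32 and −0.15, AURKA −0.29 and −0.05, and the checkpoint kinase BUB1B 0.27 and 0.14. For the G1/S and DNA replication list, 22 of 34 members lay above 0, and the median was 0.05 at percentile 95.4 by the sum and 0.07 at percentile 99.9 on exons. RFC4, a clamp loader subunit, stood at 0.50 and 0.31, and the helicase subunit MCM6 at −0.50 and 0.11. UHRF1 had 0.49 and −0.01. Replication-dependent histone genes, whose mRNAs mostly lack poly(A) tails, had 6 measured members, 3 above 0 and 3 below, with a median of 0.04 at percentile 72.5 by the sum, and were not called. On exons 6 of 8 members lay above 0 and 2 below, with a median of 0.22, above all random lists drawn. Those random lists were matched on FPKM, not on transcript length or fragment number. H2AC6 rested on 50 and 85 fragments on exons, H2AC25 on 57 and 75 and H2BC12 on 130 and 180. H2AC25 ran both ways, at 7.77 and 3.89 FPKM by the sum (−0.84, intervals apart) and 7.77 and 10.0 on exons (0.33). H2AC6 stood at 0 and 3.05 by the sum (2.02) and 5.82 and 8.22 on exons (0.43), and H2BC12 at 0.15 and 0.12. H4C3 had 0.71 and 1.46 FPKM by both measures, from 4 and 10 fragments. Such genes have near-identical copies and are uncertain. Among replacement histones, 8 of 10 members lay below 0, with a median of −0.08 at percentile 5.60, with H3-3B at 0.42 by the sum and −0.02 on exons and MACROH2A2 at −0.12 and −0.03, beside H1-10, named above.

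Cytosolic ribosomal protein genes were called lower: 31 of 43 measured members lay below 0, with a median of −0.07 at percentile 0.16, and on exons 36 of 45 with a median of −0.09, below all random lists drawn. RPL6 is named above. RPSA had −1.54 by the sum and −0.34 on exons, and RPS15 −0.71 and −0.18. RPS2 was listed at 0 in the library labelled knockdown by the sum, while its exon density was 15.4 and 18.7 FPKM (0.27). Ribosomal protein genes have many processed copies in the genome, so these values are uncertain. Mitochondrial ribosomal proteins had a median of 0.03 at percentile 76.9, with MRPL9 at 0.17 by both measures, MRPL28 at −0.17 and −0.03 and MRPS35 at 0.14 by both, beside MRPL19, named above. The nuclear respiratory chain list had a median of −0.02 at percentile 12.8 by the sum and −0.03 at percentile 2.11 on exons, where 24 of 37 members lay below 0. UQCRB, of complex III, stood at −1.08 by the sum and −0.16 on exons, COX6C at −0.38 and −0.18, NDUFB3 at 0.45 and 0.13, and UQCRFS1 at −0.29 and −0.17. No member of the mitochondrially encoded list was measured. MYC-responsive ribosome biogenesis genes had a median of 0.05 at percentile 91.5, with BOP1 at −1.07 by the sum and −0.13 on exons, SRM at −0.33 and −0.04, RRS1 at 0.32 and −0.01 and WDR12 at 0.25 and 0.12.

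Glycolysis and hypoxia genes were called lower, with 22 of 30 members below 0 and a median of −0.08 at percentile 0.99; on exons the median was −0.05 at percentile 1.79. PGAM1, phosphoglycerate mutase, stood at −1.17 by the sum and −0.34 on exons, and the glucose transporter SLC2A1 at 87.5 and 66.0 FPKM (−0.40), with −0.18 on exons. LDHA, lactate dehydrogenase, had 0.49 and −0.09, and BNIP3 −0.23 and −0.09. Cholesterol synthesis genes had a median of 0.03 at percentile 78.6; IDI1 stood at 0.43 and 0.19, STARD4 at 0.38 and 0.14 and FDPS at −0.33 and −0.13, and TM7SF2 at −0.29 by both measures. The amino acid and ATF4 response list had 18 of 25 members above 0 and a median of 0.07 at percentile 97.0 by the sum, and 0.07 at percentile 99.6 on exons. CHAC1 stood at 15.1 and 18.8 FPKM (0.30 by both measures), SLC3A2 at 0.27 and 0.08, SHMT2 at 0.24 and 0.09, and STC2 at −0.32 and 0.12.

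Immediate early genes, which respond first to growth signals, were called lower, with 18 of 27 members below 0 and a median of −0.07 at percentile 2.07; on exons 21 of 27 lay below 0, with a median of −0.05 at percentile 1.29. The call ended with TPM (median −0.15) and with a minimum of 5 FPKM (−0.07). CCN2, a matricellular protein, stood at 6.05 and 3.92 FPKM (−0.52), with −0.28 on exons, and NR4A1 at −0.38 and −0.03. ETV4 had −0.27 and −0.20, and JUNB 0.26 and −0.08. Wnt/beta-catenin targets had a median of −0.03 at percentile 33.9, with SP5 at 0.91 and 0.21, RNF43, a Wnt receptor ligase, at −0.50 and −0.14, DKK1 at 0.21 by both measures and NKD2 at 0.21 and 0.00023. NF-kB targets stood at −0.05 and percentile 22.6, with CXCL1 at 0.61 and 0.47 from 15 and 34 fragments, ICAM1 at −0.30 and −0.23, RELB at −0.27 and −0.03 and CXCL8 at 0.25 and 0.32. The p53 target list had a median of −0.02 at percentile 27.1; BAX stood at −0.34 and GDF15 at −0.25, each by both measures, and BBC3 at 0.46 and −0.18 and PHLDA3 at 0.33 and 0.01. Interferon response genes had a median of −0.05 at percentile 26.8, with IFIT1 at 0.91 by the sum and 0.05 on exons, RIGI at −0.60 and −0.01, ISG20 at 0.50 and 0.33 and USP18 at 0.41 and 0.37.

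Lists tied to the function of USP49 were not called by either measure. Writers and erasers of H2B ubiquitin had 9 of 16 members above 0 and a median of 0.0058 at percentile 48.8. WAC, which recruits the H2B ubiquitin ligase, stood at 0.87 by the sum and 0.12 on exons. ENY2, of the SAGA deubiquitinase module, had −0.77 and 0.07, with USP46 at 0.70 and 0.05 and USP7 at −0.29 and −0.07. Other ubiquitin-specific proteases had a median of 0.04 at percentile 84.9, with USP15 at 0.97 and 0.20, USP9X at 0.66 and 0.03, USP45 at −0.50 and 0.17 and USP1 at 0.22 and 0.21. PAF1 and elongation factors stood at −0.01 and percentile 31.9; CDC73 had −0.90 and 0.12, and CDK9, the kinase of P-TEFb, −0.54 and −0.10, with TCEA1 at 0.61 and −0.0029 and CCNT1 at 0.43 and 0.13. U1 and U2 snRNP proteins had a median of −0.02 at percentile 18.0, with SF3B4 at −0.66 and −0.13, SNRPF at 0.60 and 0.06, SF3A3 at −0.59 and −0.13 and SF3B3 at 0.52 and 0.02. U5 and tri-snRNP proteins stood at 0.01 and percentile 48.9, with SART1 at −0.49 and −0.20, PRPF4 at 0.36 and 0.02, DDX23 at 0.33 and 0.0042 and SNRNP200 at 0.32 and 0.03. SR proteins had a median of 0.02 at percentile 64.7, with the SR protein kinase CLK2 at −0.68 and −0.33, TRA2B at 0.42 and −0.07, SRRM2 at 0.39 and −0.09 and SRRM1 at −0.33 and −0.13. The hnRNP and other splicing regulators had 0.02 at percentile 66.1, with HNRNPU at 0.94 and 0.03, ELAVL1 at 0.89 and −0.04, HNRNPD at −0.47 and −0.04 and HNRNPF at 0.37 and 0.06. Host genes of small nucleolar RNAs sensitive to nonsense-mediated decay had a median of 0.03 at percentile 65.3, with GAS5 at −0.86 and 0.06, SNHG12 at 0.51 and −0.03, SNHG8 at −0.27 and 0.03 and ZFAS1 at 0.26 and 0.19.

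Stress and identity lists were mostly not called. Endoplasmic reticulum chaperones had a median of −0.03 at percentile 14.3, with PDIA3 at −0.53 and −0.13, SEL1L at −0.49 and 0.05, calreticulin (CALR) at −0.45 and −0.10, and CANX at −0.33 and 0.06. Heat shock proteins stood at 0.05 and percentile 82.3, with HSPD1 at −0.79 and −0.26, HSP90AB1 at 0.37 and −0.06, AHSA1 at 0.23 and 0.12 and HSPA4L at 0.22 by both. Metallothioneins and oxidative stress genes had a median of −0.01 at percentile 29.2; MT1E was listed at 0 in the library labelled knockdown by the sum, with 138 and 124 FPKM on exons (−0.16), and the next were HMOX1 at 0.19 by both, GCLM at 0.17 by both and MT2A at −0.15 by both. Autophagy and lysosome genes had a median of 0.01 at percentile 56.5, with SQSTM1 at −0.38 and −0.02, WIPI1 at −0.31 and −0.22, LAMP1 at 0.23 and −0.07 and CTSB at 0.22 and −0.06. Epithelial and intestinal genes stood at −0.07 and percentile 7.07 by the sum, and on exons were lower, with 10 of 15 members below 0 and a median of −0.14 at percentile 0.03. CDX2, an intestinal transcription factor, had −0.50 and −0.14, MUC1 −0.27 and −0.24, and KRT7 0.75 and 0.42, with ELF3 at 0.28 and −0.15. Mesenchymal genes had a median of −0.12 at percentile 8.85, with ACTA2 at −0.48 and −0.21, TWIST1 at −0.34 by both measures, FN1 at −0.14 and −0.16, and S100A4 at −0.14 by both. Markers of other cell types were scarcely measured. COL1A1 was the only measured member of the fibroblast list, at 10.5 and 7.79 FPKM by the sum and 6.93 and 6.58 on exons. CD68 was the only one of the blood and endothelium list, at 9.38 FPKM in control and listed at 0 in the library labelled knockdown, with 9.38 and 12.7 FPKM on its exons. Of genes normally silent in colon, MAGEA3, which has near-identical copies, stood at 19.2 and 17.1 FPKM by both measures and TUBB3 at 52.9 and 53.5 by the sum, with −0.13 on exons.

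**Figure D3:**
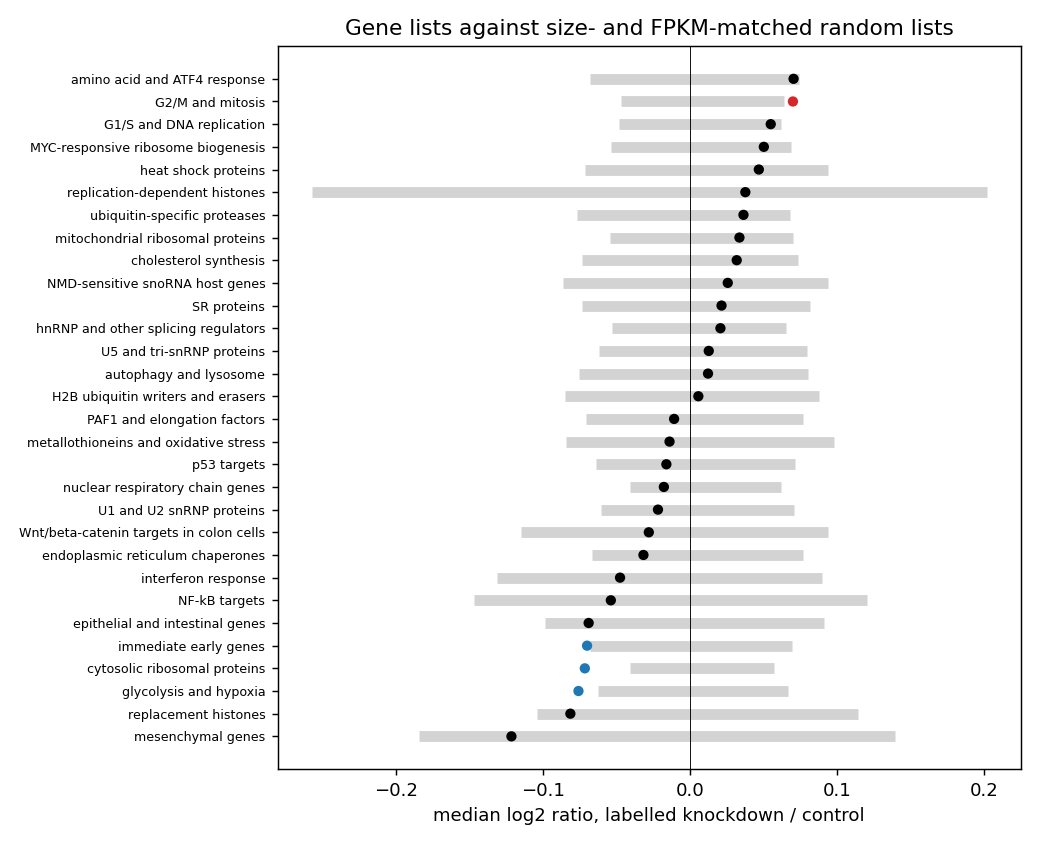
Median log2 ratio of each of 30 gene lists by the planned sum (x axis; library labelled knockdown over control; points), with grey bars holding the middle 95% of medians of 10000 matched random lists. Red marks the list called higher (G2/M, 0.07) and blue the 3 called lower; with TPM the G2/M median was −0.06.

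Gene length and exon number were named beforehand because H2B ubiquitination accompanies transcript elongation. Across genes, which are not independent, ratios had a Spearman rho of 0.12 with genomic span and 0.03 with exon number. The median ratio was −0.06 in the shortest of 10 groups by span (median 2769 bases) and 0.02 in the longest (median 197784 bases). On exons of either strand rho was 0.18 with span and 0.03 with exon number, and the medians of the shortest and longest groups were −0.05 and 0.01.

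Exon inclusion differed by 10 percentage points or more in many genes, in both directions at similar number. Of 7013 exons, inclusion was lower in the library labelled knockdown for 1564 exons of 1184 genes and higher for 1780 exons of 1261 genes. In 2735 of these exons (81.8%) the including or the skipping form was listed at 0 in a library. With RefSeq models alone, the counts were 331 lower and 379 higher. Of 1551 exons with both forms above 0 in both libraries, 284 were lower and 325 higher, or 39.3%; both of these sets were chosen after seeing the data. The 10 exons named by the rule all went between 100% and 0%, each with one form listed at 0 in each library. Inclusion was lower in BLOC1S5 (chromosome 6, 7986371 to 7986500, 130 bases), EIF4H (chromosome 7, 73241939 to 73242003, 65 bases), LARP4B (chromosome 10, 939370 to 939456), BRF1 (chromosome 14, 104778647 to 104778796), IL18 (chromosome 11, 111530908 to 111531015) and TRIP12 (chromosome 2, 230494840 to 230495564). EIF4H, a translation initiation factor, had 21.0 FPKM of including models in control and 20.4 FPKM of skipping models in the library labelled knockdown. Inclusion was higher in EIF3E (chromosome 8, 109323291 to 109323318), PITPNB (chromosome 22, 26623118 to 26623125, 8 bases), SMARCA5 (chromosome 4, 144679193 to 144679541) and DCXR (chromosome 17, 77587579 to 77587636). EIF3E, which encodes a subunit of another initiation factor, went from 101.2 FPKM of skipping models to 134 FPKM of including ones. Where the gene had an exon density, its log2 ratio lay between −0.20 (BRF1) and 0.13 (IL18).

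Intron retention was measured for 2825 introns, of which 984 were lower and 926 higher by 10 points or more in the library labelled knockdown. With RefSeq models alone the counts were 39 and 45, and of 911 introns with both forms above 0 in both libraries they were 160 and 136. Named introns again went between 100% and 0% with one form listed at 0 in each library. Retention was lower in HNRNPH1 (chromosome 5, 178977519 to 178977595, 77 bases), an hnRNP gene that had 47.2 FPKM of retaining models in control and 102 FPKM of spliced models in the library labelled knockdown. It was also lower in SLC25A3 (chromosome 12, 97511650 to 97511887), RPLP0 (chromosome 12, 119119121 to 119119507) and GAS5 (chromosome 1, 172099837 to 172100017). It was higher in RRBP1 (chromosome 20, 17588010 to 17588279) and TUFM (chromosome 16, 28762924 to 28763135). Of 7012 genes with 2 or more transcripts, the most abundant transcript differed in 1040 (14.8%), and in 1959 with no minimum share. Models that join genes count under each gene, so these numbers can hold the same model more than once. With RefSeq models alone 314 differed.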

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

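The comparison of the sum with exon density and the count of exons with a form at 0 were tests chosen after the result was seen; the simulations of counting noise and the length-matched lists were set before. Parts of the libraries outside the planned gene sum were compared as shares of recovered fragments, with Wilson 95% intervals that cover counting error only. The assembled models among them can still enter the exon densities. Assembled models that join 2 or more genes held 0.466% of fragments in the library labelled knockdown (0.463 to 0.469) and 0.414% in control (0.411 to 0.417). The mitochondrial genome held 1.23% (1.22 to 1.23) against 1.18% in control (1.17 to 1.18), relative to the total on the other chromosomes. Unspliced assembled models held 4.32% (4.31 to 4.32) against 4.46% in control (4.45 to 4.47), and spliced assembled models with no gene name 0.972% (0.968 to 0.977) against 1.03% (1.03 to 1.04). Haplotype and unplaced sequences held 0.0529% (0.0519 to 0.0539) against 0.0537% (0.0526 to 0.0548). The first 2 parts were above the control level beyond counting error, the next 2 below it, and they stand out for that reason only.

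The first pattern weighed was the 396 genes past 2-fold by the planned sum. Counting noise alone gave a median of 19.5 such genes and at most 27 in 100 simulated pairs. This argues only against counting noise on a fixed set of models. The simulation leaves out errors of assigning fragments to models and differences between the assemblies. By density on RefSeq exons of either strand, 16.9% of the 396 stayed past 2-fold in the same direction. The same fragments lying on different models in the libraries would give such a low share. That density spreads fragments evenly over the same models, so it is not a separate check. The source of most of the pattern is therefore not settled. The genes that stayed past 2-fold remain open, and an effect of the knockdown stays untested, with 1 library per group and the direction of USP49 depending on how fragments are assigned.

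The second pattern was the 3344 exons whose inclusion differed by 10 points or more. Counting noise gave a median of 5 and at most 15 in 100 simulated pairs. This argues only against counting noise on a fixed set of models at these depths. Both simulated libraries held the control models, so noise acting through the separate assembly of each library was not simulated. In 81.8% of the exons a form was listed at 0 in a library. True absence of the form and a model missing from that library's assembly would give the same value, so they cannot be told apart. Of exons with both forms in both libraries, 39.3% differed, against a median of 0.163% from counting noise; division of fragments between models may add to this and was not simulated, and a change in splicing with the knockdown stays untested.

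The third pattern was the small shifts of 4 gene lists. Random lists were then matched on FPKM and transcript length. Against them, cytosolic ribosomal proteins stood at percentile 0.17, glycolysis and hypoxia genes at 1.01 and immediate early genes at 1.19. This argues against a trend with transcript length as the whole cause. G2/M genes stood at 97.6, too close to the upper limit to tell; the rule that the percentile must clear the limit by 2 SE of the random draw was set after this value was seen. Genomic span, which had a rho of 0.12 with the ratios across genes, was not matched. A trend with span was therefore not tested for any of these lists. About 1.5 of 30 lists of random genes would be called. Lists whose members vary together may be called more often. Differences in growth state or handling between the cultures, and the knockdown itself, may each shift such lists and cannot be separated with 1 library per group.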

How the results depend on the processing

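The gene measures other than the planned sum, values without depth scaling, fragment counts at USP49, RefSeq models alone and events with both forms in both libraries were chosen after seeing the data; the other settings were fixed beforehand. No paired analysis was possible because each group had 1 library, and no library was left out for the same reason. Depth limits low genes most: USP49 rested on 206 and 69 fragments by the sum and 46.5 and 69 on exons.

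By the sum, the USP49 ratio of −0.89 kept its direction under each setting fixed beforehand. It was −1.31 with a pseudocount of 0.1, −0.37 with 5 and −0.12 with TPM, the pseudocount setting the size. These settings all count the same models, so they could not test how fragments are assigned to USP49. The TPM value lay close to the median of all genes under TPM, −0.10. On exons of either strand the USP49 ratio was reversed, at 0.15. As log2 ratios of fragments with no pseudocount it was −1.86 on models named USP49 and −0.084 with the unnamed model counted. TPM left 4546 genes measured of 11645 and a median of −0.10, because 97.9% and 98.1% of the summed values lay on models under 300 bases that held 0.34% and 0.31% of the fragments. Without depth scaling the median was 0.26.

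Counts of genes past 2-fold, 184 higher and 212 lower in the plan, were 73 and 99 with a pseudocount of 5, 85 and 98 from 5 FPKM, 414 and 483 at a ratio of 1.5 and 6 and 13 with TPM. They were 52 and 77 on exons of the gene's strand, 37 and 58 on either strand, 1 and 3 on models with the same introns, and 1 and 2 with the same introns and length. Without depth scaling 308 were higher. The higher genes made up 46.5% in the plan, 31.6% with TPM, 64.7% without depth scaling, and 25% and 33.3% in the last 2 exon measures, which held few genes. The other settings fixed beforehand left these counts within 1.5 times. The outer 2.5% of ratios began at −0.64 and 0.63 from 5 FPKM, −0.97 and 0.86 with a pseudocount of 0.1, where r was 0.890, and −0.31 and 0.25 on exons of either strand. There, rho with genomic span was 0.175.

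The calls of cytosolic ribosomal proteins, G2/M and glycolysis were kept in 8 of 8 alternatives and that of immediate early genes in 6. The latter call ended with TPM (−0.15) and from 5 FPKM (−0.065). Median centring, upper-quartile scaling and TPM multiply a library by a constant. They can change a call only through the pseudocount, the minimum FPKM and the matching, so these alternatives are weak checks. Under TPM the G2/M median was reversed, at −0.064, with the shift of all genes. On exons 4 lists were higher and 5 lower; those added were replication-dependent histones (0.22), amino acid and ATF4 response (0.067), G1/S (0.071), nuclear respiratory chain (−0.033) and epithelial genes (−0.14); the cause was not tested. Among named genes, the exon measure reversed KRT10 (0.31), DESI2 (0.094), CD59 (0.024), ARL3 (−0.00041), UBQLN2 (−0.047), NUMBL (−0.21) and ZNF830 (−0.023). The cause was not tested gene by gene.

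Exons lower and higher numbered 622 and 654 from 20 FPKM, 955 and 1070 at 20 points, 331 and 379 with RefSeq models alone, and 284 and 325 with both forms in both libraries. For introns the counts were 362 and 321, 605 and 600, 39 and 45, and 160 and 136 in the same order. The most abundant transcript differed in 1592 genes from 1 FPKM, 413 from 20 FPKM, 1959 with no minimum share and 314 with RefSeq models alone. Exon and intron counts from 1 FPKM stayed within 1.5 times. Leaving out transcripts under 5% of their gene says nothing about stability, since it removed 16 models above 0 and otherwise models listed at 0. These sets differ in size by construction.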

Other observations

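The genes and events here were chosen after their values were seen, and none of the tests was planned. Genes whose fragments lay on models with the same introns and similar length in both libraries gave a comparison less exposed to differences between assemblies. A gene whose models differed was left out by construction, so a low count follows partly from that choice. Only 3 of 3910 genes with the same introns and similar length were past 2-fold: ENO1-AS1 (−1.47 on the log2 scale), HIGD1B (−1.47) and PHC1 (1.58). Each shares exonic bases with another gene, so its fragments cannot be assigned to it alone. Among 2516 such genes of mean 5 FPKM or more that share no bases, ranked by the log2 ratio of exon FPKM with a pseudocount of 1, which understates low genes, the first at the low end was TMSB10 (−0.60), thymosin beta 10, an actin-binding protein. It had 5370 fragments in control and 4309 in the library labelled knockdown, a depth-scaled ratio of 0.658 (exact 95% interval 0.632 to 0.685). ANKRD36BP1 (also −0.60), a pseudogene with near-identical copies, had the lower fragment ratio, 0.613 from 249 and 186 fragments (0.504 to 0.744). IFI6, an interferon-induced gene, stood at 0.732 (0.579 to 0.924) and OLFM2 at 0.728 (0.596 to 0.890). At the high end of the same ranking, FBXO16 (0.36) had a fragment ratio of 1.34 (1.04 to 1.74), from 99 and 162 fragments. COA1, of mitochondrial complex assembly, stood at 1.23 (1.12 to 1.34), CPNE8 at 1.22 (1.11 to 1.34), CSTA, a cysteine protease inhibitor, at 1.21 (1.09 to 1.34), and DNAJB4, a co-chaperone, at 1.21 (1.11 to 1.32). These are the extremes of many genes, so their intervals are not adjusted for the choice.

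Some exons differed with both forms above 0 in both libraries. Inclusion was lower in the library labelled knockdown for an exon of CCDC150 (chromosome 2, 197285646 to 197285708), at 76.3% in control and 11.9%. An exon of RAP1A, a Ras-related GTPase (chromosome 1, 111971615 to 111971708), stood at 72.3% and 12.02%, and an exon of NFE2L1, a transcription factor of proteasome genes (chromosome 17, 43489393 to 43489482), at 71.4% and 21.6%. Inclusion was higher for an exon of PLEKHM2 (chromosome 1, 15920411 to 15920470), at 13.6% and 78.3%. An exon of RNF8, a ubiquitin ligase of the DNA damage response (chromosome 6, 37450374 to 37450463), stood at 20.2% and 79.8%. Intron retention was lower in CDK5RAP3 (chromosome 17, 43408019 to 43408233), at 85.9% and 11.7%, and in HNRNPL, a splicing regulator (chromosome 19, 44022857 to 44022967), at 62.1% and 11.3%. It was higher in METTL5 (chromosome 2, 170389397 to 170389537), at 34.3% and 79.7%. These levels come from fragments divided between models and have no replicate.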
